A study of Homo sapiens with 4 samples.

How the data were processed

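Total RNA of MDA-MB-231 cells was measured on 4 Affymetrix arrays, 2 of cells labelled shDROSHA and 2 of control cells labelled shNC. MDA-MB-231 is an established human breast carcinoma cell line. Groups and replicate numbers were taken from the sample titles, which call the replicates biological. The design text calls the control mock-transfected, whereas the labels read shNC, and which of these describes the control cells was not settled here. Per the labels' protocols, RNA was extracted with Trizol, column-purified, amplified with a whole-transcript kit and hybridised as biotin-labelled single-stranded cDNA.

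The deposited values are log2 signals, 1 per probe set and array. Per the submitters' processing notes the authors used RMA, which corrects background, normalizes quantiles between arrays and summarises probes into probe sets. The software version and any filter on probe sets are not given in the sources used here. The sorted values of single arrays differed from their mean over the arrays by up to 0.119 on the log2 scale, so the rows used were not exactly quantile-normalized as a set. Because RMA gives arrays nearly the same distribution, a change shared by most transcripts would not be seen in these values. No detection calls were used, so a dim probe set can reflect background, and fold changes of dim probe sets are compressed.

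All 18603 probe sets were tested, and 0 of them were control probe sets. The platform annotation gave 15886 of them 1 gene symbol, 0 several and 2717 none. All 15886 were matched by Entrez identifier to the RefSeq table of GRCh38.p14, from which the symbols printed here come, and they stand for 15870 genes, 15506 of them protein-coding and 264 long non-coding. A probe set without a symbol is unnamed here and is not thereby without a gene. No coordinates are printed, because the build behind the values is not given in the sources used here.

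The comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values of the 4 arrays, with Benjamini-Hochberg adjustment over all probe sets and a threshold of adjusted p 0.05. Every adjusted p printed for a gene comes from limma. Before the data were examined, the design, the alternatives, the gene lists and the rule for naming genes were fixed. That design takes 1 constant prior variance for all probe sets, called the constant fit here. A prior variance that follows signal level, called the trended fit, was among the alternatives fixed in advance. It is reported beside the constant fit throughout because the counts of the 2 fits proved very different, and that prominence, with the alternatives run on the trended fit, was decided after seeing the counts. In the text, rose, fell and changed are said of single genes that passed the trended fit unless another test is named. The SEs printed are those of the constant fit unless the trended fit is named beside them, so they are not the errors behind the trended calls. The residual SD within groups fell from 0.213 in the dimmest of 5 equal bins of probe sets to 0.067 in the brightest. The constant fit had 3 prior degrees of freedom and the trended fit 11.9, added to 2 residual degrees of freedom. With 2 arrays against 2, an exact permutation test of 1 gene cannot give a two-sided p below 0.333, so the calls rest on spread pooled across genes. The number of arrays limits the precision.

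Genes were named by this rule: DROSHA, up to 12 higher and 12 lower genes, up to 4 members of each list with the smallest p, and DGCR8, DICER1, XPO5, AGO2, HMGA2, PDCD4, MCM7 and VMP1. The 12 per direction had 1 symbol, arrays of the groups that did not overlap, and a higher group mean at or above the median of all probe sets. They were to be those past the threshold with the largest change. As no named gene passed the constant fit, all 24 places were filled in order of unadjusted p, as the rule provides. No named probe set was found for DGCR8, PDCD4 and VMP1, which were not analysed here.

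Of the 22 gene lists, 21 had 5 or more measured members and were tested with camera of limma at a preset inter-gene correlation of 0.01, with adjustment over the 21. A gene with several probe sets counted once, by its brightest. Alternatives were an estimated correlation, fry, which tests whether a list's genes move one way without comparing them with other genes, and the trended fit. With an estimated correlation, camera takes its p from the 2 residual degrees of freedom, so few lists could pass whatever their correlation. Each list's median was also set against 10000 random lists of the same size matched on signal level in 20 bins. Further alternatives covered robust priors, filters on dim probe sets, fold minimums of 2 and 1.5, a threshold of 0.1, further normalization, the replicate number as a block, 1 probe set per gene and leaving out each array. The planned test of microRNA seed sites needs 3′ UTR sequences and was not run.

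The fits were tested on simulated data of the comparison of shDROSHA with shNC, with 18603 genes of which 200 changed, in 20 simulations. The constant fit recovered 0.05% of genes changed by 0.5 log2 units and 8.7% of those changed by 1, with 0.568% of its calls false. The trended fit recovered 42.2% and 90.4%, with 5.08% false. Without any change, the constant fit made a mean of 0 calls and the trended fit 0.05. The simulated spread depended on signal level and genes were independent, which favours the trended fit and leaves shared variation between genes untested. In simulated data of 15870 genes, camera called 100% of lists of 30 genes shifted by 0.15 and 0.5% of unshifted lists. Figures were drawn with matplotlib 3.10.9.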

Results

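The mRNA of MDA-MB-231 cells, a mesenchymal-like human breast carcinoma line, was measured on 4 arrays. In 2 of them the cells carried a short hairpin RNA against DROSHA (shDROSHA), and in 2 they were the control, labelled shNC. DROSHA is the nuclear ribonuclease that cuts primary microRNA transcripts. The comparison asks which mRNAs differ in level when it is depleted. Median log2 signals were 7.21 and 7.21 in the shDROSHA arrays and 7.25 and 7.24 in the shNC arrays, and all signals lay between 3.35 and 13.59. Across probe sets, which are not independent replicates, Pearson's r was 0.9937 between the shDROSHA arrays, 0.9945 between the shNC arrays and 0.9896 to 0.992 between groups.

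DROSHA mRNA was 1.98-fold lower in the shDROSHA arrays, at 8.73 ± 0.027 against 9.71 ± 0.073 (log2 mean ± SD, n = 2 each). Its log2 fold change was -0.99 with an SE of 0.087 in the constant fit, from which all SEs come unless the trended fit is named, and both knockdown arrays (8.71 and 8.74) lay below both controls (9.66 and 9.76). The adjusted p was 0.0843 in the constant fit and 3.89e-06 in the trended fit. The other components fixed in advance differed less and passed neither fit: DICER1 was higher by 0.30 (SE 0.126), AGO2 by 0.21 (SE 0.084) and XPO5 by 0.19 (SE 0.187). The DICER1 difference was 0.15 without shNC replicate 2 and 0.45 without shNC replicate 1. The XPO5 difference was -0.03 without shNC replicate 1, 0.05 without shDROSHA replicate 1, 0.34 without shDROSHA replicate 2 and 0.42 without shNC replicate 2.

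Across the array, the number of genes past the threshold depended on how the spread was modelled. The constant fit called 1 probe set, unnamed here (TC1100013152.hg.1), which was 10.5-fold higher in shDROSHA (log2 fold change 3.40, SE 0.133, adjusted p = 0.0314), and 0 named genes, the lowest named adjusted p being 0.0617. At an unadjusted p under 0.05 it had 2774 probe sets. The trended fit called 1192 probe sets, 581 higher and 611 lower, of which 1073 were named, and 39 differed at least 2-fold (14 higher and 25 lower). From the dimmest to the brightest of 5 equal bins of signal, it called 31, 72, 175, 332 and 582 probe sets. How many members of a list rose or fell therefore depends on their signal level, and such counts do not compare lists. In simulated data the constant fit recovered 0.05% of genes changed by 0.5 log2 units and 8.7% of those changed by 1. A count of 0 members in that fit, given for the lists below, therefore does not speak against a shift of the list. With each array centred on its median, 62.5% of the trended calls were higher, against 48.7% as deposited. The trended count was 535 without shNC replicate 1, 748 without shNC replicate 2 and 1949 without shDROSHA replicate 1. The constant count was 0 without any 1 of the 4 arrays (1739 to 2776 at unadjusted p under 0.05), where the lone array was assumed to vary like the other group. The groups did not overlap at 8885 probe sets (47.8%), against 33.3% by chance.

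**Figure D1:**
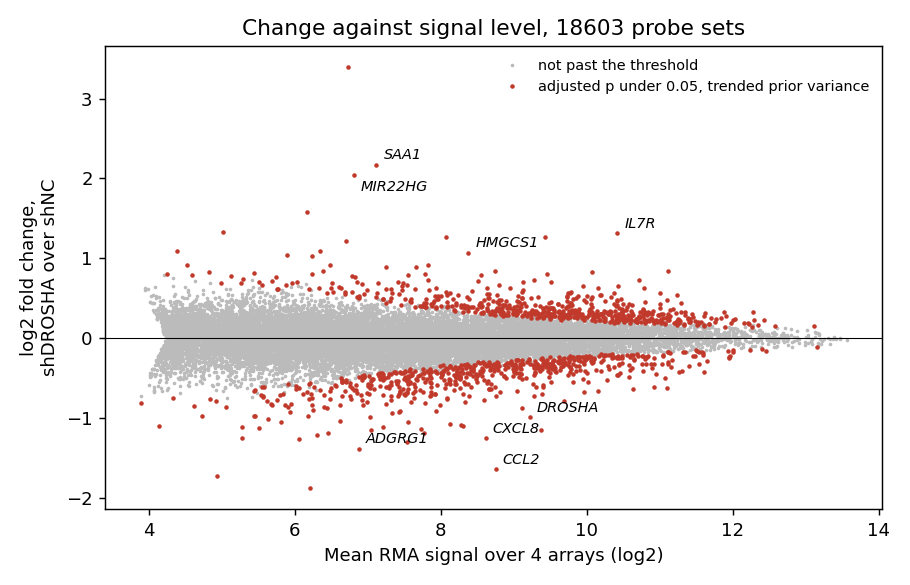
The log2 fold change of shDROSHA over shNC is plotted against the mean log2 signal over the 4 arrays, 1 point per probe set, with the 1192 probe sets past adjusted p 0.05 in the trended fit in red. The spread narrows with signal, and DROSHA, CCL2 and IL7R lie outside the bulk at their level.

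The higher genes with the smallest p included a microRNA host transcript, secreted and surface proteins and sterol enzymes. All 12 passed the trended fit and none the constant fit. MIR22HG, the long non-coding host transcript of miR-22, was 4.12-fold higher (7.83 ± 0.225 against 5.79 ± 0.003, log2 mean ± SD, n = 2 each). SAA1, an acute-phase serum amyloid protein with near-identical paralogs that its probes may not tell apart, was 4.51-fold higher (log2 fold change 2.17, SE 0.156). IL7R, the alpha chain of the interleukin-7 receptor, was 2.49-fold higher and EFEMP1, an extracellular matrix glycoprotein, 2.41-fold. HMGCS1, MSMO1 and IDI1, enzymes of cholesterol synthesis, were 2.10-fold, 1.78-fold and 1.78-fold higher. SEMA3E, a secreted semaphorin, was 1.89-fold higher, LPAR1, a lysophosphatidic acid receptor, 1.75-fold, and EREG, a ligand of the epidermal growth factor receptor, 1.65-fold. NAA15, a subunit of an N-terminal acetyltransferase, and MZT1, a component of gamma-tubulin complexes, were 1.66-fold and 1.62-fold higher.

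Among the 12 lower genes, DROSHA was joined by chemokines and signalling proteins, and again all passed the trended fit and none the constant fit. CCL2, a monocyte-attracting chemokine, was 3.12-fold lower (7.93 ± 0.087 against 9.57 ± 0.135, log2 mean ± SD, n = 2 each). CXCL8, a neutrophil-attracting chemokine, was 2.39-fold lower, and ADGRG1, an adhesion receptor, 2.61-fold lower (log2 fold change -1.39, SE 0.081). AKAP12, a scaffold of protein kinase A, was 2.28-fold lower and PDE7B, which breaks down cyclic AMP, 2.22-fold. AKR1C3, a steroid-converting aldo-keto reductase with close paralogs, was also 2.22-fold lower. KIAA0040, MSANTD4 and TC2N were 2.20-fold, 2.12-fold and 2.08-fold lower. CYFIP2, a component of the WAVE actin-regulating complex, was 1.99-fold lower and PMEPA1, a TGF-beta-induced membrane protein, 1.90-fold.

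**Figure D2:**
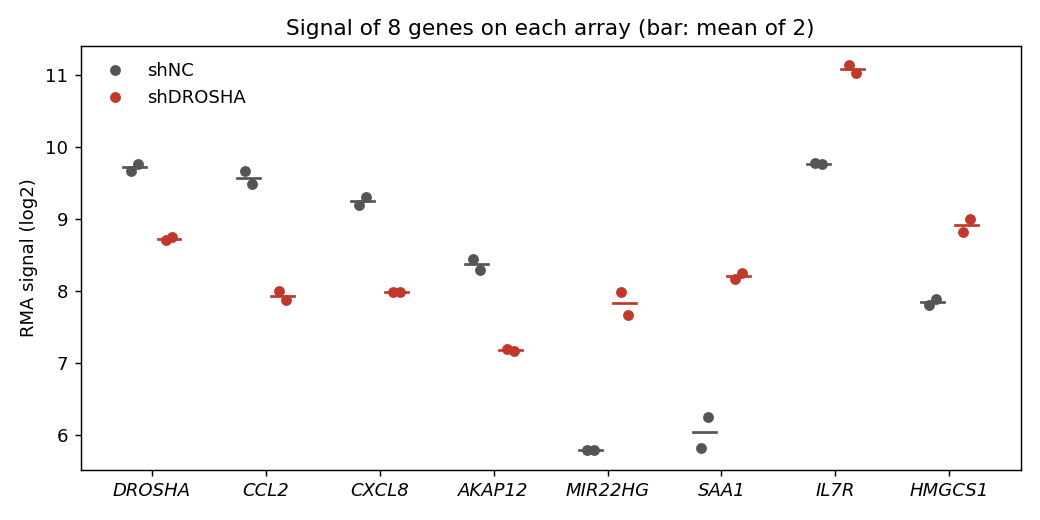
Log2 RMA signals of 8 genes on each array are shown as points, grey for shNC and red for shDROSHA, with a bar at the mean of 2. The arrays of the groups do not overlap for any of the 8 genes, which the rule that named them required. DROSHA lies at 8.71 and 8.74 against 9.66 and 9.76.

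Genes of cholesterol and lipid synthesis were higher as a group. Of 28 measured members, 11 rose, 2 fell and 15 did not pass the trended fit, and the median log2 fold change was 0.22. HMGCS1 rose by 1.07 (SE 0.1), MSMO1 by 0.84 (SE 0.079), IDI1 by 0.83 (SE 0.09) and ELOVL6, a fatty acid elongase, by 0.66 (SE 0.088). The 2 that fell were ABCA1 (-0.53) and ABCG1 (-0.71), which export cholesterol from cells and were singled out after their values were seen. In the constant fit 0 changed over all genes tested, whereas 10 rose and 2 fell adjusted over the list alone. The list was called by camera (adjusted p = 5.6e-07) and by fry (adjusted p = 0.0044). The camera call was lost with an estimated correlation (adjusted p = 0.32 with an estimated correlation). That correlation was -0.036, below the preset 0.01, so the loss does not show that the genes of the list vary together.

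Cell cycle genes were also higher. Of 35 members 31 were higher, 14 rose, 0 fell and 21 did not pass the trended fit, with a median of 0.17. CCNA2 and CCNB1, the cyclins A2 and B1 of S phase and mitosis, rose by 0.47 (SE 0.085) and 0.34 (SE 0.093), and MCM6, a subunit of the replicative helicase, by 0.47 (SE 0.081). Over all genes 0 changed in the constant fit, and 3 rose adjusted over the list alone. The camera adjusted p was 5.6e-07, against adjusted p = 0.32 with an estimated correlation and 0.058 with fry. Replication-dependent histones, whose mRNAs accumulate in S phase, were not called with them: of 39 members 0 rose and 1 fell, H2BC14 (-0.18, SE 0.083 in the constant fit and 0.044 in the trended fit), and the median was -0.09. The constant fit called 0 of the histones over all genes and 0 adjusted over the list alone. Their camera adjusted p was 0.12, and 0.02 with the trended fit. It was adjusted p = 0.69 with an estimated correlation, and 0.5 with the trend and an estimated correlation together. The median lay at the 0.13 percentile of level-matched random lists.

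Ribosome biogenesis factors shifted in the same direction. Of 32 members 29 were higher, 6 rose, 0 fell and 26 did not pass, with a median of 0.15. UTP20 and LTV1, factors of small-subunit assembly, rose by 0.48 (SE 0.081) and 0.34 (SE 0.082), and DDX21, a nucleolar helicase, by 0.26 (SE 0.083), while RRS1 was lower by a log2 fold change of -0.26 without passing. The constant fit called 0 of them over all genes and 0 adjusted over the list alone. The camera adjusted p was 1e-05, against adjusted p = 0.32 with an estimated correlation and 0.058 with fry.

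Type I interferon response genes were lower. Of 34 members 25 were lower, 9 fell, 1 rose and 24 did not pass, with a median of -0.18. DDX60 (-0.92, SE 0.113), RIGI, a sensor of viral RNA (-0.72, SE 0.091), and IFIT2, an interferon-induced antiviral protein (-0.55, SE 0.082), fell, and SAMD9L rose by 0.52 (SE 0.083). In the constant fit 0 changed over all genes, and 8 fell and 1 rose adjusted over the list alone. The camera adjusted p was 0.0015, against adjusted p = 0.32 with an estimated correlation and 0.025 with fry. Of 27 NF-kB cytokines and inflammatory genes, 0 rose and 5 fell, among them CCL2 (-1.64), CXCL8, TNFAIP3 (-0.52) and NFKBIA (-0.31), the latter pair being NF-kB-induced inhibitors of NF-kB. Over all genes 0 of these changed in the constant fit, and 2 fell adjusted over the list alone. That list was not called by camera (adjusted p = 0.12), was called with the trended fit (0.02), without the probe sets below the median signal and without shDROSHA replicate 2, and had a median of -0.04. It was not called with an estimated correlation (adjusted p = 0.69 with an estimated correlation, and 0.5 together with the trend).

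**Figure D3:**
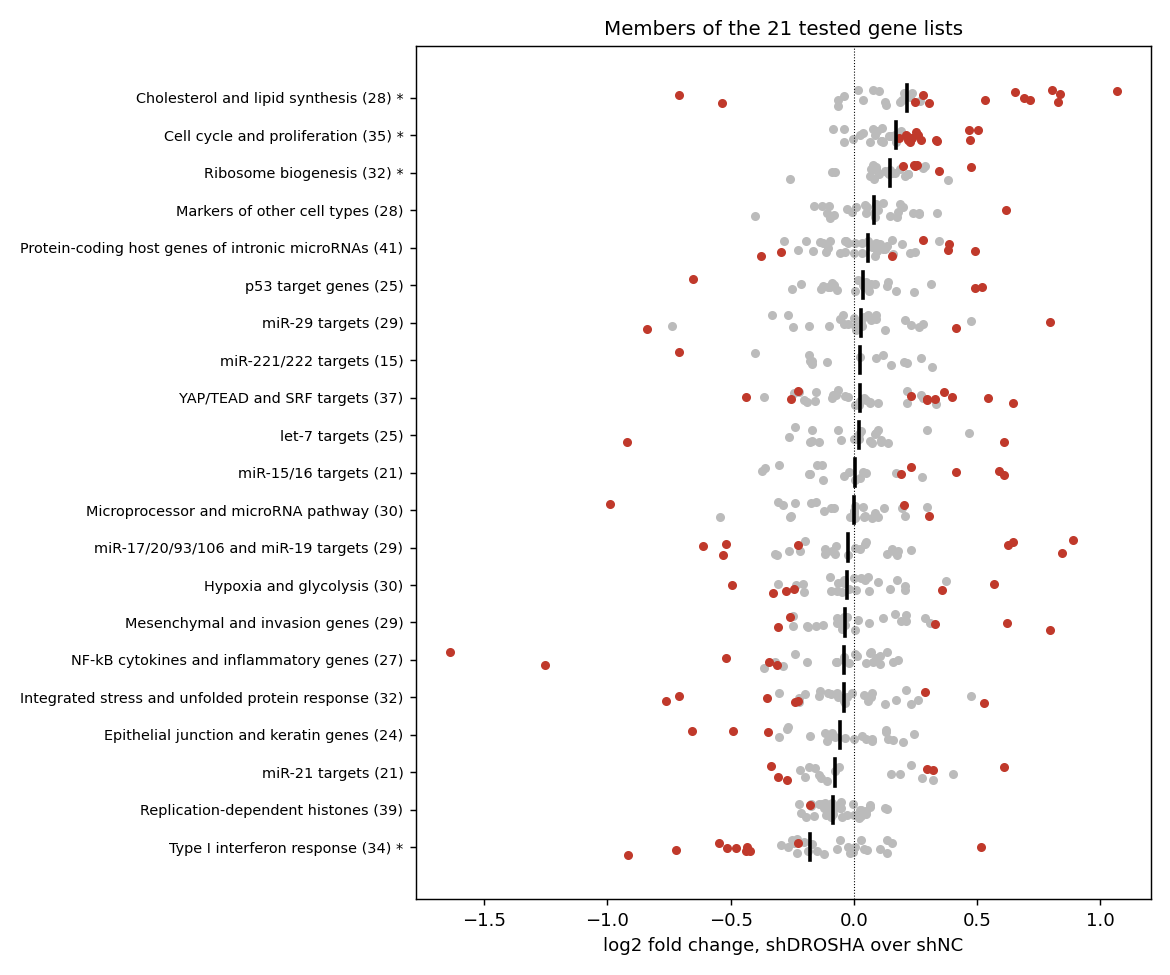
Each point is the log2 fold change of 1 list member, shDROSHA over shNC, with members past adjusted p 0.05 in the trended fit in red and the list median as a bar. The number of measured members is in brackets, and an asterisk marks the 4 lists called by camera at the preset correlation, 3 higher and 1 lower.

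Of 30 genes of the Microprocessor and microRNA pathway, 2 rose and 1 fell. DROSHA fell, CNOT7, a deadenylase subunit, rose by 0.31 (SE 0.093), and AGO4 was lower by a log2 fold change of -0.54 (SE 0.103) without passing the trended fit. Adjusted over the list alone, 2 fell in the constant fit, DROSHA and AGO4, against 0 over all genes. The median was 0.001 and the mean -0.06, camera's direction was down (adjusted p = 0.64), and fry called the list lower (adjusted p = 0.046). That call includes DROSHA itself, the targeted gene: without it the mean of the other 29 was -0.03, 17 of them were higher, and fry did not call the list (adjusted p = 0.14). Among 41 protein-coding host genes of intronic microRNAs, 5 rose and 2 fell, with SEPTIN2 rising by 0.49 (SE 0.096) and MEST by 0.39 (SE 0.112), and 0 changed in the constant fit over all genes or adjusted over the list alone (camera adjusted p = 0.34). MCM7, the host of the miR-106b cluster, was higher by 0.15 (SE 0.087) without passing either fit, and by 0.10 without shNC replicate 1. Of the 34 long non-coding host transcripts fixed in advance only MIR22HG and MIR99AHG had a named probe set, too few for a test. Whether unnamed probe sets measure any of the others is not known. MIR99AHG differed by 0.01 (SE 0.098), and by -0.06 to 0.08 when single arrays were left out.

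None of the 6 lists of microRNA targets was called by camera. The let-7 targets (25 measured, 1 rose and 1 fell, adjusted p = 0.75) included CDC25A, a cell cycle phosphatase, which rose by 0.61 (SE 0.081), and E2F5, which fell by 0.92 (SE 0.117), while HMGA2 differed by 0.02 (SE 0.083), and by -0.02 to 0.06 when single arrays were left out. Of 29 targets of miR-17, its relatives and miR-19, 4 rose and 4 fell (adjusted p = 0.95), with THBS1 rising by 0.84 (SE 0.105), TXNIP by 0.89 (SE 0.135) and LIMK1 falling by 0.61 (SE 0.093). Of 21 miR-15/16 targets 5 rose and 0 fell (adjusted p = 0.57), among them WEE1 (0.59, SE 0.123) and CDK6 (0.41, SE 0.093). The others were CDC25A, CHEK1 (0.23) and KIF23 (0.19), the latter pair named after their values were seen. All 5 act in the cell cycle, so their rise cannot be told apart here from that of the cell cycle genes. Of 29 miR-29 targets 2 rose and 1 fell (adjusted p = 0.58), with SPARC, a matrix protein, rising by 0.80 (SE 0.119) and TDG, a DNA glycosylase, falling by 0.84 (SE 0.091). Of 21 miR-21 targets 3 rose and 3 fell (adjusted p = 0.82), and of 15 miR-221 and miR-222 targets 0 rose and 1 fell (adjusted p = 0.89), DDIT4 (-0.71, SE 0.116). CDC25A is a member of the let-7, miR-21 and miR-15/16 lists, and CDK6 of the miR-29 and miR-15/16 lists. Each is counted as rising in every list that holds it, so the counts of these lists are not separate responses. In the constant fit 0 members of the 6 lists changed over all genes. Adjusted over the list alone, 4 rose and 3 fell for miR-17 and miR-19, 3 rose for miR-15/16, 1 rose and 1 fell for let-7 and for miR-29, 1 rose for miR-21 and 2 fell for miR-221 and miR-222. Medians and means differed in sign for miR-21 (-0.08 and 0.03, camera up), miR-17 and miR-19 (-0.03 and 0.02, camera up) and miR-221 and miR-222 (0.03 and -0.04, camera down).

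The remaining 7 lists were not called by camera. YAP/TEAD and SRF targets held 8 that rose and 3 that fell of 37, with F3 (0.65, SE 0.096) and ANKRD1 (0.55, SE 0.106) rising, and were called by fry alone (adjusted p = 0.014, camera 0.34). Of 24 epithelial junction and keratin genes 0 rose and 3 fell, ITGB4 (-0.66, SE 0.083), CLDN4 (-0.49, SE 0.092) and KRT19 (-0.35, SE 0.09), with a camera adjusted p of 0.57. Of 29 mesenchymal and invasion genes 3 rose and 2 fell (adjusted p = 0.65, median -0.04, mean 0.04, camera up), with S100A4 rising by 0.62 (SE 0.094). Of 25 p53 targets 2 rose and 1 fell (adjusted p = 0.64), of 32 integrated stress and unfolded protein response genes 2 rose and 5 fell (adjusted p = 0.56), and of 30 hypoxia and glycolysis genes 2 rose and 4 fell (adjusted p = 0.69). Of 28 markers of other cell types 1 rose, TFF1 (0.62, SE 0.156), and 0 fell (adjusted p = 0.22). In the constant fit 0 members of these 7 lists changed over all genes. Adjusted over the list alone, 1 YAP/TEAD and SRF target rose, 2 epithelial genes fell, 2 mesenchymal genes rose, 1 p53 target rose and 1 fell, 2 stress genes fell, and 0 changed among hypoxia genes and markers of other cell types.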

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

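The trended fit with a further choice, the trend with an estimated correlation and the Microprocessor list without DROSHA were added after seeing the data; the other alternatives were planned. In the constant fit, the count of 1 (1 higher, 0 lower) became 1192 with an intensity trend (581 and 611), 542 without probe sets below the median signal (221 and 321), 60 without those below the lower quartile (23 and 37), 8 with 1 probe set per gene (2 and 6), 27 at adjusted p 0.10 (10 and 17), 0 with quantile normalization again (2828 at unadjusted p under 0.05 in limma), and 0 without any 1 array (1739 to 2776). With the replicate number as a block it was 0 (2490 at unadjusted p under 0.05 in limma), and the trended count was 1391. The correlation of same-numbered arrays' deviations was -0.022, so no shared replicate effect was seen. Whether same-numbered cultures were prepared together is not given in the sources used here. The trended count was 39 at 2-fold or more (14 and 25), 245 at 1.5-fold (82 and 163), 1824 at adjusted p 0.10 (878 and 946), and 535 to 1949 without 1 array (249 to 885 higher, 286 to 1064 lower): 535 without shNC replicate 1, 748 without shNC replicate 2 and 1949 without shDROSHA replicate 1. The looser threshold and the fold minimums act by construction. Residual SD fell from 0.213 in the dimmest of 5 bins of signal to 0.067 in the brightest, so 1 constant prior variance overstates the spread of bright probe sets. That bears on the higher counts with a trend and without dim probe sets. The block and leaving out an array also leave fewer residual degrees of freedom than the 2 of the main fit. The causes of the other differences were not tested. DROSHA was at -0.99 in both fits and passed only the trended one.

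Lists called by camera fell from 4 to 0 with an estimated correlation, where p rests on 2 residual degrees of freedom. With the trend added the 4 had a camera adjusted p = 0.24 each. Without DROSHA the Microprocessor list had adjusted p of 0.85 by camera and 0.14 by fry. The 4 were called again without probe sets below the median, with the block, trend, cyclic loess and mean of probe sets, and without each array. Fry called 2 of them, cholesterol and interferon. Leaving out single arrays reversed log2 fold changes of XPO5 (-0.03 without shNC replicate 1, to 0.417), HMGA2 (-0.017 without shDROSHA replicate 2, to 0.058) and MIR99AHG (-0.062 without shNC replicate 2 and -0.046 without shDROSHA replicate 1, to 0.081), none past the threshold. List directions reversed only in uncalled lists, with these adjusted p: without probe sets below the median, Microprocessor 0.89, let-7 0.89 and miR-21 0.64; with the trend, at either correlation, miR-21 0.95; with the block, miR-17 and miR-19 0.97; without single arrays, let-7 0.81 and 0.97 (range 0.49 to 0.97), miR-17 and miR-19 0.57 and 0.97 (0.53 to 0.97), miR-221 and miR-222 0.92 (0.71 to 0.96) and hypoxia 0.96 (0.49 to 0.96). The median log2 fold change of all probe sets was 9e-04 as deposited and at most 0.0339 after quantile normalization, centring or cyclic loess. The seed site test and its alternatives were not run. Without detection calls, how far dim probe sets lie above background is not known.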

Other observations

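The tests of other splits of the arrays and of single array pairs were chosen after the results were seen, and the looks at long non-coding RNAs, gene span, host genes and symbol families were prompted by exploring the data. Of 264 long non-coding genes measured, 3 rose and 0 fell in the trended fit: MIR22HG (2.04), THAP9-AS1 (0.34) and CRNDE (0.30), named after their values were seen. Of the 264, 7 hold an annotated microRNA gene within their span, on either strand, and 1 of these, MIR22HG, rose. The 7 include ARL2-SNX15, SERF2-C15ORF63 and FKBP1A-SDCBP2, whose symbols join those of coding genes, so not all are dedicated microRNA hosts. Grouping genes by the letters that open their symbols gave 76 families of at least 20 members, of which camera called 0, with a lowest adjusted p of 0.32 and 10 at an unadjusted p under 0.05.

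Protein-coding genes spanning the longest stretches were slightly lower. In 10 equal bins of genomic span, the median log2 fold change was 0.013 in the shortest genes and -0.036 in the longest. There 35 rose and 96 fell in the trended fit as deposited. The next longest bin was at -0.017, and span was not tested. Such counts depend on scaling, as centring each array on its median put the median of all probe sets at 0.0339.

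The lists for cholesterol synthesis, cell cycle and ribosome biogenesis were higher and the interferon list lower. A shift of all genes of their signal level does not account for this: no random list of matched level among 10000 had a median above that of the 3 higher lists (percentiles 100, 100 and 100) or as low as the interferon list (percentile 0). Nor does 1 array carry it: in each of the 4 lists the mean went the list's way in all 4 pairs of a shDROSHA with a shNC array, 16 comparisons that share the same 4 arrays. Depletion of DROSHA and an off-target effect of the hairpin stay open, as do genes of a list varying together with culture density or growth. No test here tells these apart. Whether the control cells carried a hairpin was not settled here, so it is not known whether effects common to any hairpin were controlled for. With an estimated correlation 0 lists were called, but on 2 residual degrees of freedom that loss does not show that genes varied together. The estimated correlations were -0.036 for cholesterol, -0.008 for interferon, 0.044 for cell cycle and 0.035 for ribosome biogenesis genes.

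Release of microRNA targets from repression would raise their mRNAs. The 129 measured targets of the 6 lists had a median of 0.02 and lay at the 92.1 percentile of level-matched lists, whose middle 95% ran from -0.041 to 0.03, with 12 that rose and 10 that fell in the trended fit. The value lies between the bounds set beforehand, so a small release and none cannot be told apart with these hand-picked lists. Dim targets were kept, such as LIN28B (log2 means 4.15 in shDROSHA and 4.39 in shNC), and a target at background cannot show a release. DROSHA mRNA was also lowered 1.98-fold, not removed. MicroRNA levels were not analysed here.

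Coding genes that hold an annotated microRNA gene were slightly lower: 711 such genes had a median of -0.03 against 0 in 14780 others, 15 rose and 37 fell in the trended fit against 487 and 524 of the others, and their median was lower than that of the others in all 4 array pairs. Holding was judged by position on the chromosome alone, on either strand. These genes are also longer, with a median span of 84.9 kb against 25.3 kb. Among random lists of other genes matched on span and level their median lay at the 1.43 percentile, 0.002 below the lower bound of -0.028. A median below that bound was set beforehand as going against long genes being lower, with or without a microRNA. A further requirement, a margin above the bootstrap SE of 0.0077, was added after the percentile was seen and was not met. The random lists have the same size, so their bounds already hold the sampling spread of such a median. By the bound set beforehand the median argues against span and level alone accounting for the shift, but only narrowly. The 41 host genes fixed beforehand had a median of 0.057. The middle 95% of level-matched random lists ran from -0.06 to 0.066, so these 41 were not set apart in either direction.

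Other splits of the 4 arrays into pairs are too few for a share under 0.05. The real split gave 1192 genes in the trended fit and 1 in the constant fit, the highest of the others gave 0 in each, and 1 of the 3 splits, the real one, reached the real count in each. Each of the others puts 1 shDROSHA and 1 shNC array on both sides, so any difference between the groups widens its spread within sides. Their counts of 0 therefore do not show what would be called without a difference.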
